A study of Rattus norvegicus with 11 samples.

How the data were processed

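Liver RNA of 11 Wistar rats was measured on 11 Affymetrix oligonucleotide arrays, with 1 array per animal. Per the labels, 3 arrays came from control animals (numbers 1, 2 and 9) and 8 from animals given the high dose of mequindox (numbers 2, 3, 4, 5, 6, 8, 10 and 11), a quinoxaline N-oxide antibacterial used in animals. The dose in units of mass and the length of treatment were not given in the sources used here. All animals were labelled with an age of week 9 except high-dosed animal 8, labelled week 10. Per the series' design text, these 2 groups were taken to arrays on the basis of a principal component analysis of aqueous liver extracts and of changes in clinical chemistry, so they were not chosen blind to other measurements. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made by the standard Affymetrix protocol.

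The values used were the deposited intensity of each probe set on a linear scale, from 1 to 34328, for 31099 probe sets, of which 57 were Affymetrix control probe sets. Per the submitters' processing notes MAS5 was used, with no version and no role named. The deposited table gave no detection calls and did not state a scaling target. Its 2% trimmed means ran from 504.9 to 542.9 between arrays rather than at 1 shared value, so it stayed unknown whether and how the authors had scaled the arrays to each other, and the values were used as deposited. No pair of arrays held identical values, and 100 of all values stood at the lowest value of 1. For arrays no sequencing depth exists; the number of arrays, 3 of them controls, limits the precision.

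Values were transformed as log2(intensity + 55.26), where the pseudocount was the 20th percentile of all values, so that a fold change is on this scale and understates the change of dim genes. The Affymetrix control probe sets and probe sets under the 40th percentile of mean log2 signal (7.40) were left out, which left 18625. The filter used the mean over all arrays, so the mean of 1 group could lie under it; among the genes named this held for Pbsn, Per3, Irs1, Tyms and Bub1 in controls and for Abcg5 and Hspa4l in high-dosed animals, and the sizes of their changes are less certain. Gene names came from the platform annotation and were checked by Entrez identifier against the RefSeq gene table of assembly GRCr8. Of all probe sets, 20832 had 1 gene symbol, 436 had several and 9831 had none listed; 20764 of those with 1 symbol matched the gene table and 0 symbols changed. No gene was named from a probe set with several symbols. A gene was represented by its probe set of 1 symbol with the highest mean signal, which gave 10714 genes. No genome build was named for the array, so no coordinates are given. Among the called genes 327 had more than 1 tested probe set, and in 91 of these at least 1 other probe set had a fold change of the opposite sign.

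High-dosed animals were compared with controls in limma 3.58.1 under R 4.3.3, with a linear model per probe set and moderated variances with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over the probe sets or genes tested. A change was called at an adjusted p below 0.05, and calls with at least a 2-fold change were counted as well. Positive log2 fold changes are higher in the high-dosed animals. All adjusted p of genes below are from this limma fit. In total 43 gene lists for liver pathways, drug and stress responses and liver cell types had been fixed before the data were examined, as had the main design, the alternatives and the rule for naming genes. The 42 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and limma's fry beside it, adjusted over the 42 lists; the neutrophil list had 3 measured members and was not tested. Each animal's list score was the mean over members of log2 signal relative to the 11 arrays, and the groups' scores were compared by an exact two-sided permutation test over all 165 arrangements of the 11 animals, for which the smallest possible p is 0.00606. Array quality measures were the signal percentiles, the 3' to 5' signal ratios of the beta-actin and Gapdh control probe sets, spike-in signals, rank correlations and principal components.

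The genes named were the 12 with the largest rise and the 12 with the largest fall among called genes with all 8 high-dosed animals on the same side of the control mean, leaving out placeholder symbols; up to 4 called members of each list that passed, by adjusted p, and up to 2 called members of any other list, with at most 60 genes from lists; and 18 fixed sentinel genes of drug, stress and metabolic responses. This gave 90 genes with a value. Of the sentinels, 1 is not reported here, Cyp2b1 shared its probe set with another gene and was not analysed here, and the probe set of Mki67 lay under the signal filter. Genes named outside this rule are said to be so, and 24 such genes were run under the same alternatives.

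The fit was tested on simulated data with the means and spreads of this comparison and 18625 probe sets, 200 of them changed in each of 5 runs. It called 57.2% of the probe sets changed by 0.5 on the log2 scale and 95.6% of those changed by 1, and 6.26% of its calls were false. A simulated shift of -0.20 of 1 list was found in 5 of 5 runs with 0 other lists called; the simulated genes were independent of each other, which the real ones are not. Alternatives were no pseudocount or the 40th percentile as pseudocount, no filter or the 60th percentile, quantile normalization, median centring, other variance models, array weights per group, the mean of all probe sets of a gene, an exact permutation test per probe set, and each array left out in turn. Settings added after seeing the data were the animal number (8 and above against 6 and below) as a block, each of these number ranges alone, the high-dosed animals 8, 10 and 11 left out together, and the beta-actin ratio as a covariate.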

Results

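Liver gene expression was measured in 3 control rats and 8 rats given the high dose of mequindox, 1 array per animal, to ask how the drug changed expression in this tissue. The study chose these groups for arrays with knowledge of other measurements on the animals. The median intensity per array ran from 149 to 186.6. Of 16 array quality measures and principal components 0 differed between the groups after adjustment and 3 had an unadjusted p below 0.05 (exact two-sided permutation tests, lowest adjusted p = 0.097, for the second component). That component separated the groups fully and stood at the smallest possible exact permutation p, 0.00606. Adjusted over 16 measures, 1 measure at that p could not pass, so the count of 0 does not show that the groups were alike.

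Genes of the circadian clock were among those with the largest changes, and they went both ways. The nuclear receptors Nr1d2 and Nr1d1, which repress transcription of Bmal1, rose 5.56-fold and 4.56-fold (log2 fold change 2.48 ± 0.18 and 2.19 ± 0.15, SE, 3 control and 8 high-dosed animals, limma adjusted p = 2.09e-05 for both). Dbp, a transcription factor driven by the clock, rose 7.03-fold (2.81 ± 0.56, limma adjusted p = 0.00861), and the period gene Per3 rose by 1.37 ± 0.30 (limma adjusted p = 0.0149). Cry1, a clock repressor, and Bmal1, an activator at the core of the clock, fell by 2.05 ± 0.18 and by 1.70 ± 0.38 on the log2 scale (limma adjusted p = 0.000121 and 0.0167). For each of these 6 genes all 8 high-dosed animals lay on the same side of the control mean, which the rule for naming the largest changes required. Of the 18 measured members of the clock list, 5 rose, 5 fell and 8 did not pass; adjusted over the list alone, 5 rose and 7 fell. The other called members, named after their values were seen, were Tef (0.99), which rose, and Nfil3 (-0.57), Rora (-0.49) and Per1 (-0.47), which fell. The list as a whole was not shifted (camera adjusted p = 0.149), and its mean log2 fold change of 0.049 differed in sign from its median of -0.37 and from the test. Over the other settings that mean ran from -0.0642 to 0.206, and the list was not called in any of them. The call of Bmal1 was lost without control 1 (-1.67, adjusted p = 0.0812), and within animal numbers 8 and above, with 1 control, its value was -1.03. That of Per3 was lost without control 1 (1.43) or 2 (highest adjusted p = 0.0593). Without control 1 the calls of Tef, Nfil3, Rora and Per1 were lost too (adjusted p from 0.0594 to 0.187). Those of Tef and Per1 were also lost without most other single arrays and without a filter. That of Rora was lost without control 2 or 9 or after quantile normalization, and that of Tef after quantile normalization, after median centring or without a variance trend.

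**Figure D1:**
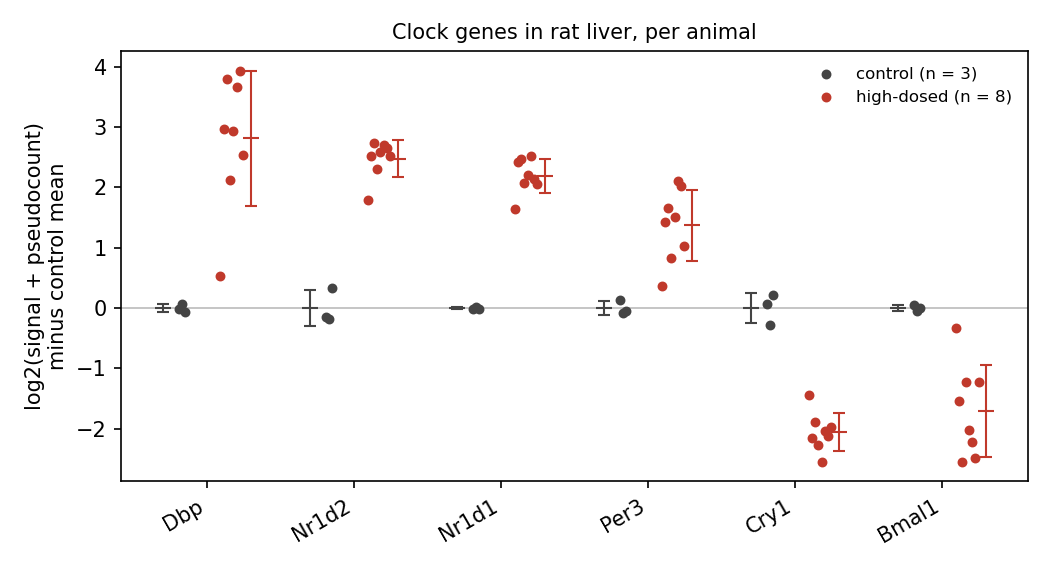
Log2 signal (intensity plus pseudocount) of 6 clock genes in each animal, relative to the mean of the control animals on the vertical axis, with controls in grey (n = 3) and high-dosed animals in red (n = 8); bars show mean and SD. Dbp, Nr1d2, Nr1d1 and Per3 lay above the control mean and Cry1 and Bmal1 below it in all 8 high-dosed animals, which the rule for naming them required.

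Among the largest rises outside the clock list, Sds, the serine dehydratase, rose 4.39-fold (log2 fold change 2.13 ± 0.36, limma adjusted p = 0.00394). Hsd17b2, which oxidises estradiol and testosterone, rose 4.16-fold (2.06 ± 0.27, limma adjusted p = 0.00117), and Cyp17a1, a steroid hydroxylase and lyase, rose 3.34-fold (1.74 ± 0.45, limma adjusted p = 0.0306). The remaining large rises were the unconventional myosin Myo7b (1.80), the protease inhibitor A2m (1.53), the pantetheinase Vnn1 (1.42) and the phospholipase Pla2g12a (1.38). Pbsn, encoding probasin, was called as higher too (limma adjusted p = 0.00719), but its control mean of 6.28 on the log2 scale lay under the filter value of 7.40 and was not shown to be above background. The size of its rise was therefore not determined (2.51, and 4.09 without a pseudocount). The largest falls besides Cry1 and Bmal1 were Lifr, the receptor of leukaemia inhibitory factor (-2.07 ± 0.35), and Abcg5, part of a sterol exporter into bile (-1.96 ± 0.26), with limma adjusted p of 0.00427 and 0.00128, although the high-dosed mean of Abcg5 (7.07) lay under the filter value too. Hsd11b2, which inactivates glucocorticoids, fell by 1.46 and the cytochrome Cyp3a9 by 1.46. Ppp1r3b, which targets a phosphatase to glycogen, fell by 1.49 and Tubb2a, a beta-tubulin, by 1.69. Cdkn1a, the cyclin-dependent kinase inhibitor p21, fell by 1.49 ± 0.32 (limma adjusted p = 0.0122), and Mest (-1.53), Tsku (-1.39) and Nat8 (-1.31) completed the 12 largest falls. The calls of Cyp17a1 and Cdkn1a were lost without control 1 (adjusted p = 0.0982 and 0.0588), Cyp17a1 also without control 2 or 9 and Cdkn1a without control 9. Their log2 fold changes without control 1 were 1.85 and -1.5. The call of Vnn1 was lost without control 9 (adjusted p = 0.0601). Within animal numbers 8 and above, with 1 control, the values were 1.31 for Sds, -0.979 for Lifr, -1.21 for Abcg5 and -0.772 for Nat8, none of them called (adjusted p from 0.0744 to 0.268).

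In all, 1141 of 10714 genes changed, 847 higher and 294 lower in the high-dosed animals, and 40 of them changed at least 2-fold (23 higher and 17 lower). For probe sets the counts were 1288 of 18625, with 862 higher and 426 lower, and 63 at least 2-fold. In 1132 of the 1141 genes all 8 high-dosed animals lay on the same side of the control mean, which their being called made likely. The groups did not overlap for 12.06% of the genes tested, where chance gives 1.21%. The share of higher calls depended on the scaling. It was 74.2% of genes and 66.9% of probe sets as deposited. It was 64% (591 higher and 332 lower) and 57.5% (700 and 517) after quantile normalization, and 64.7% (473 and 258) and 55.8% (530 and 420) after median centring. The counts leaned on single controls. Limma called 325 genes and 324 probe sets without control 1, and 759 genes and 729 probe sets without control 2. Without control 9 it called 548 genes and 570 probe sets as higher. All 1141 genes kept the direction of their fold change in each of the 3 settings. Since they had been called on the same arrays, this was likely from the outset and is no separate support. With high-dosed animals 8, 10 and 11 left out, a setting chosen after the data were seen, 716 genes were called. With the animal number (8 and above against 6 and below) as a block 1955 probe sets and 1520 genes were called. Within numbers 6 and below (2 controls and 5 high-dosed animals) the counts were 761 and 612, and within 8 and above, with 1 control taken to vary like the high-dosed animals, 17 and 3.

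The list of genes of the proteasome, the complex that degrades ubiquitin-tagged proteins, was shifted down. All 30 measured members had a log2 fold change below 0, as deposited and after quantile normalization or median centring, 14 of them fell and 16 did not pass; adjusted over the list alone, 25 fell. The mean log2 fold change was -0.21 (camera adjusted p = 1.17e-16, and adjusted p = 0.125 with an estimated correlation). Psmd1 (-0.47 ± 0.055), Psmc5 (-0.35 ± 0.061), Psmd14 (-0.52 ± 0.10) and Psmb3 (-0.24 ± 0.050) had the smallest limma adjusted p, from 0.000533 to 0.0101. The list score was 0.15 ± 0.065 in controls (SD, n = 3) and -0.058 ± 0.029 in high-dosed animals (SD, n = 8), without overlap. The exact permutation p was 0.00606, the smallest possible, and 0.0636 after adjustment. Without control 1 the call of Psmd14 was lost (adjusted p = 0.068) and without control 2 that of Psmb3 (adjusted p = 0.0506).

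The lists of ER stress genes and of heat shock proteins were shifted down with the preset correlation. Of 26 measured members of the ER stress and amino acid response list 7 fell, 0 rose and 19 did not pass (9 fell and 0 rose adjusted over the list alone), and 6 had a log2 fold change above 0. Among those that fell were Hspa5, the main ER chaperone (-0.28 ± 0.057), the calcium-binding chaperone Calr (-0.28 ± 0.046), Creld2 (-0.66 ± 0.10) and Sdf2l1 (-0.43 ± 0.095), with limma adjusted p from 0.00239 to 0.0149. The list's mean was -0.15 (camera adjusted p = 5.61e-05, and adjusted p = 0.391 with an estimated correlation). Of 17 heat shock proteins 6 fell, 0 rose and 11 did not pass (8 fell and 0 rose adjusted over the list alone), and 4 had a log2 fold change above 0. The falls included Hspa4l (-0.60 ± 0.089), Hsph1 (-0.60 ± 0.13), Hspa4 (-0.29 ± 0.063) and Hspe1 (-0.22 ± 0.045), with limma adjusted p from 0.002 to 0.0135. That list's mean was -0.16 (camera adjusted p = 0.000222, and adjusted p = 0.391 with an estimated correlation), and -0.101 with the filter at the 60th percentile. Without control 1 the calls of Sdf2l1, Hspe1, Hsph1 and Hspa4 were lost (adjusted p from 0.0543 to 0.0808). Sdf2l1 was also lost without control 2 (adjusted p = 0.0641) and Hsph1 without control 9.

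Lists of genes of antigen presentation, macrophages and endothelium were shifted up. Of 9 measured genes of antigen presentation on MHC class II 6 rose, 0 fell and 3 did not pass (8 rose and 0 fell adjusted over the list alone). They included RT1-Da (0.70 ± 0.17), the invariant chain Cd74 (0.53 ± 0.13), RT1-DMa (0.60 ± 0.17) and RT1-DMb (0.52 ± 0.14), with limma adjusted p from 0.0233 to 0.0402. The list's mean was 0.55 (camera adjusted p = 0.000222, and adjusted p = 0.549 with an estimated correlation). Of 18 markers of Kupffer cells and macrophages 1 rose, the mannose receptor Mrc1 (0.31 ± 0.091, limma adjusted p = 0.0459), 0 fell and 17 did not pass. Adjusted over the list alone, 7 macrophage markers rose (mean 0.26, camera adjusted p = 0.00705, and adjusted p = 0.715 with an estimated correlation). Of 15 endothelial markers 3 rose, Emcn (0.55 ± 0.10), Pecam1 (0.60 ± 0.11) and Stab2 (0.40 ± 0.10), 0 fell and 12 did not pass. Adjusted over the list alone, 8 endothelial markers rose (mean 0.21, camera adjusted p = 0.0116, and adjusted p = 0.549 with an estimated correlation). Of 16 hepatocyte markers 1 rose, Apoa1 (0.35 ± 0.078), 1 fell, Asgr1 (-0.18 ± 0.044), and 14 did not pass, the same adjusted over the list alone (mean -0.0014, camera adjusted p = 0.438). That mean turned sign when any 1 of 4 arrays was left out. The calls of Apoa1 and Asgr1 were lost without control 1 (adjusted p = 0.0737 and 0.156) and that of Apoa1 without control 9, and that of Asgr1 without a variance trend (adjusted p = 0.0552).

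Control 1 stood low for the macrophage and MHC class II lists, with a macrophage score of -0.49 and an MHC class II score of -0.78, against -0.054 and -0.20 in control 2 and -0.032 and -0.22 in control 9. Without control 1 the macrophage list's mean was 0.115 (adjusted p = 0.21) and the MHC class II list's 0.36 (adjusted p = 0.00346). In that setting the calls of RT1-Da, Cd74, RT1-DMa, RT1-DMb, Mrc1, Stab2 and Pecam1 were lost (adjusted p from 0.0541 to 0.271), and the log2 fold changes of the first 4 were 0.456, 0.336, 0.376 and 0.343. The endothelial list was not called without control 9 (adjusted p = 0.0867) or within numbers 6 and below (adjusted p = 0.072), nor the macrophage list within numbers 8 and above (mean 0.168, adjusted p = 0.0893). The calls of RT1-DMb, RT1-DMa, Mrc1 and Stab2 were each also lost without another control and without at least 1 high-dosed animal, and after quantile normalization (adjusted p from 0.0523 to 0.0687). Those of RT1-DMa, Mrc1 and Stab2 were lost after median centring, those of RT1-DMa and Mrc1 without a filter, and that of Mrc1 without a variance trend.

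**Figure D2:**
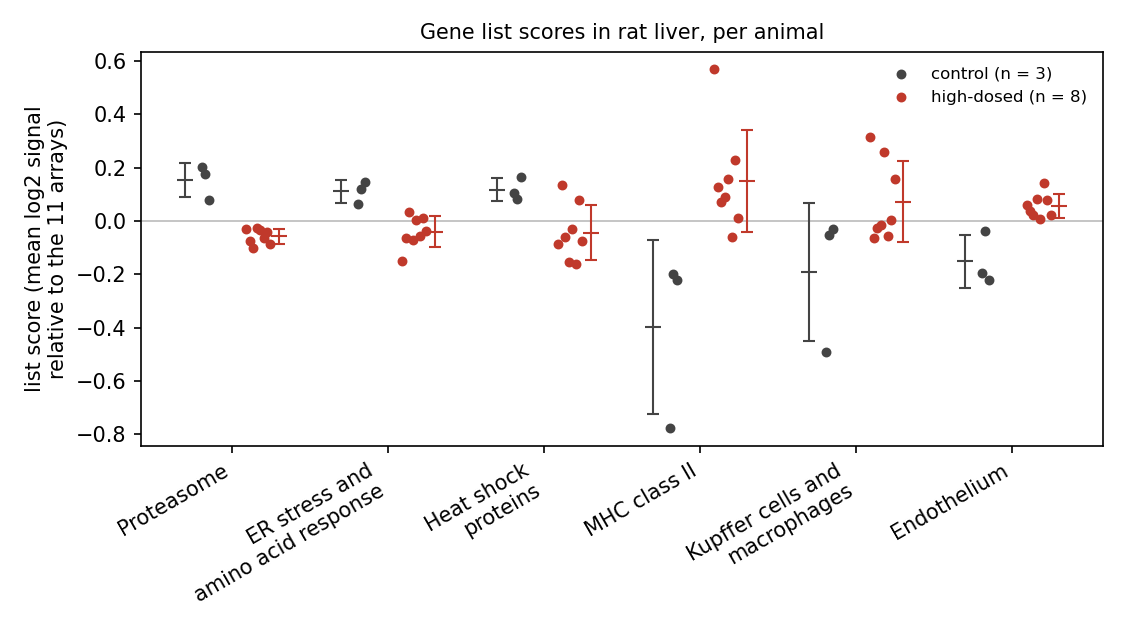
Score of 6 gene lists in each animal (mean over members of log2 signal relative to the 11 arrays, vertical axis), with controls in grey (n = 3) and high-dosed animals in red (n = 8); bars show mean and SD. For the proteasome all 8 high-dosed animals lay below all 3 controls, and control 1 had the lowest MHC class II and macrophage scores, at -0.78 and -0.49.

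Some drug-metabolising genes differed between the groups. Of 20 measured targets of the nuclear receptors CAR and PXR 5 rose, 1 fell and 14 did not pass, the same adjusted over the list alone. The rises included the canalicular exporter Abcc2 (0.48 ± 0.074), the basolateral exporter Abcc3 (1.18 ± 0.27) and the aldehyde dehydrogenase Aldh1a1 (0.75 ± 0.16), and the fall was Cyp3a9 (-1.46 ± 0.25), with limma adjusted p from 0.00244 to 0.0188. The list's mean was 0.26 (camera adjusted p = 0.00729, and adjusted p = 0.715 with an estimated correlation). It was 0.145 and not called without control 2 (adjusted p = 0.267) and 0.417 without control 1 (adjusted p = 5.44e-09). The list score of control 1 (0.126) lay among those of the high-dosed animals (-0.051 to 0.237), against -0.419 in control 2 and -0.274 in control 9. Control 1 also lay within the high-dosed range for Abcc3 (log2 signal 9.75 against 9.51 to 10.07) and Aldh1a1 (12.54 against 12.47 to 12.94), but not for Abcc2 (12.39 against 12.66 to 13.06). The calls of Abcc3 and Aldh1a1 were lost without control 2 or 9 (highest adjusted p = 0.0909).

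Cyp1a1 (0.67 ± 0.40), Cyp1a2 (-0.081 ± 0.039), Cyp3a23-3a1 (0.24 ± 0.18) and Cyp4a1 (-0.016 ± 0.11) did not pass, with limma adjusted p from 0.213 to 0.941, and the last turned sign without control 1 (0.11), without high-dosed animal 2 or 3 and within numbers 8 and above (0.141). Without control 1 Cyp1a1 was 1.10, Cyp1a2 -0.0527 and Cyp3a23-3a1 0.518, and without control 9 Cyp1a1 was 0.363 and Cyp3a23-3a1 0.0743, none of them called (adjusted p from 0.107 to 0.851). Cyp3a23-3a1 was 0.132 without control 2 (adjusted p = 0.784). Of 7 measured targets of the aryl hydrocarbon receptor 1 rose, 1 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.779). Of 16 genes on a list set for N-oxide reduction, which also holds genes with other roles, 2 rose, 3 fell and 11 did not pass (2 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.779). The fall of Nqo1, a quinone reductase (-0.51 ± 0.13, limma adjusted p = 0.0249), stood in both lists. Named after their values were seen, the other called members were Nfe2l2 (0.29), encoding Nrf2, which rose in the first list, and 4 in the second. Of these, Fmo1 (1.33), a flavin monooxygenase that oxidises drugs rather than reducing N-oxides, and the cofactor gene Mocs1 (0.41) rose. Mocs2 (-0.45) and the xanthine dehydrogenase Xdh (-0.29) fell. The calls of Nqo1, Nfe2l2, Mocs1 and Xdh were lost without control 1 (adjusted p from 0.12 to 0.223), those of Nqo1, Nfe2l2 and Xdh also without control 2 and those of Mocs1 and Xdh without control 9. Those of Nfe2l2 and Xdh were further lost when any 1 of 5 high-dosed animals was left out or after median centring, Nfe2l2 also after quantile normalization and Xdh without a variance trend.

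The lists of the Nrf2 response and of p53 and DNA damage were not called by camera, but fry called both as moving up on balance (adjusted p = 0.021 and 0.00303). Of 22 measured genes of the Nrf2 response 3 rose, 1 fell and 18 did not pass (6 rose and 1 fell adjusted over the list alone). The rises were led by sulfiredoxin Srxn1 (0.91 ± 0.10) and metallothionein Mt2A (1.07 ± 0.14), with limma adjusted p of 0.000388 and 0.00119. Mt2A also stood in the list of glucocorticoid targets. The other of 2 Srxn1 probe sets had the opposite sign. The list had 17 members with a log2 fold change above 0 and a mean of 0.24 (camera adjusted p = 0.0618, and adjusted p = 0.549 with an estimated correlation). It was called in 7 of 27 other settings, among them the 2 changes of scaling, no filter and control 1 left out (mean 0.325, adjusted p = 0.000115), and its highest adjusted p with 1 array left out was 0.269, without control 2 (mean 0.188). Hmox1 (0.36 ± 0.11) and Gclc (-0.080 ± 0.099) did not pass, with limma adjusted p of 0.0583 and 0.656, and the sentinel Nqo1 fell, as given above. Hmox1 passed without high-dosed animal 2 (adjusted p = 0.0324) or 5 (adjusted p = 0.0209), with the animal number as a block (adjusted p = 0.0436) and with the beta-actin ratio as a covariate (adjusted p = 0.0224). Gclc turned sign without control 1 (0.0106) and was -0.162 without control 9. Of 22 targets of p53 and DNA damage genes 5 rose, 1 fell and 16 did not pass (5 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.23). The death receptor Fas (0.64 ± 0.082), the apoptosome component Apaf1 (0.42 ± 0.087) and the cyclin Ccng1 (0.42 ± 0.11) rose, with limma adjusted p from 0.00105 to 0.0264, as did Zmat3 (0.46) and Mgmt (0.41), named after their values were seen, while Cdkn1a fell. Mdm2 did not pass (0.19 ± 0.098, limma adjusted p = 0.243), and the other of 2 Fas probe sets had the opposite sign. Without control 1 the calls of Apaf1, Ccng1, Zmat3 and Mgmt were lost (adjusted p from 0.0882 to 0.271), those of Ccng1 and Mgmt also without control 2 or 9 and that of Zmat3 without control 2. That of Mgmt was also lost when any 1 of 6 high-dosed animals was left out, with the higher pseudocount, without a filter, after either change of scaling, without a variance trend or with the beta-actin ratio as a covariate.

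In the cell cycle list 4 of 25 genes rose, 0 fell and 21 did not pass (5 rose and 0 fell adjusted over the list alone, camera adjusted p = 0.149). The list was called in 3 of 27 other settings, no filter (adjusted p = 0.03), numbers 6 and below, and animals 8, 10 and 11 left out. The genes that rose were the microtubule regulator Stmn1 (0.89 ± 0.16) and the replication helicase subunit Mcm4 (0.49 ± 0.095), with limma adjusted p of 0.00549 and 0.00777, and, named after their values were seen, Tyms (0.39) and Bub1 (0.27), which were 0.585 and 0.406 without a pseudocount. The calls of Mcm4, Tyms and Bub1 were lost without control 1 (adjusted p from 0.0593 to 0.263), that of Tyms also without control 2 or 9. That of Bub1 was further lost without control 2, when any 1 of 7 high-dosed animals was left out, with the higher pseudocount, without a filter or after either change of scaling.

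In bile acid synthesis and transport 6 of 25 genes rose, 1 fell and 18 did not pass (7 rose and 1 fell adjusted over the list alone), and the list's mean was 0.14 (camera adjusted p = 0.0618, and adjusted p = 0.715 with an estimated correlation). The list was called in 7 of 27 other settings, among them the 2 changes of scaling, no filter, the filter at the 60th percentile (mean 0.24, adjusted p = 0.0227) and control 1 left out (mean 0.22, adjusted p = 0.000199). It was 0.0908 without control 9 (adjusted p = 0.158), and the highest adjusted p with 1 array left out was 0.337, without control 2 (mean 0.105). The sterol 12-alpha-hydroxylase Cyp8b1 rose 2.14-fold (1.10 ± 0.13, limma adjusted p = 0.000727) and Abcg5 fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (0.73 ± 0.22, limma adjusted p = 0.0526), but did without control 1 (1.13, adjusted p = 0.00372), with the filter at the 60th percentile (adjusted p = 0.0468) and with the animal number as a block (adjusted p = 0.0386). It was 0.487 without control 9 (adjusted p = 0.23).

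Of 36 targets of PPAR alpha and genes of fatty acid oxidation 3 rose, 2 fell and 31 did not pass (3 rose and 3 fell adjusted over the list alone). Vnn1 and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation (0.81 ± 0.22, limma adjusted p = 0.0351), rose, as did Acads (0.22), named after its value was seen. Pdk4, which restrains pyruvate oxidation (-0.68 ± 0.12, limma adjusted p = 0.00544), and Decr2 (-0.32 ± 0.075, limma adjusted p = 0.0194) fell. The list's mean was -0.073 (camera adjusted p = 0.0197, and adjusted p = 0.778 with an estimated correlation). It was -0.0032 and not called without control 1 (adjusted p = 0.288), and -0.0412 and not called without high-dosed animal 3 (adjusted p = 0.0877). The mean was -0.124 without high-dosed animal 6, -0.153 without control 9, -0.181 within numbers 6 and below, and 0.133 within numbers 8 and above, where it was not called (adjusted p = 0.237). The calls of Cpt1a, Decr2 and Acads were lost without control 1 (adjusted p from 0.108 to 0.131), those of Cpt1a and Acads also without control 2 or 9 (highest adjusted p for Cpt1a 0.116) or without high-dosed animal 4 or 8. That of Acads was further lost when any 1 of 3 more high-dosed animals was left out, after either change of scaling or without a variance trend.

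Of 21 genes of gluconeogenesis and glycogen 7 rose, 2 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 0.79). They included the rise of Sds and the fall of Ppp1r3b. Named after their values were seen were rises of Slc37a4 (0.54 ± 0.074), which moves glucose 6-phosphate into the ER, and Ugp2 (0.58 ± 0.11), which makes UDP-glucose, and a fall of Pgm1 (-0.30 ± 0.059), with limma adjusted p from 0.00139 to 0.00803. Pck1 (0.015 ± 0.062), Fasn (-0.25 ± 0.15) and Alb (0.0012 ± 0.018) did not pass, with limma adjusted p of 0.905, 0.324 and 0.973, and Pck1 and Alb turned sign after median centring, Pck1 also without control 2 or high-dosed animal 6, and Alb without control 9 or high-dosed animal 4 or 5 and within numbers 6 and below.

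Among called members of other lists, the enzymes Asl (0.66), Glud1 (0.17), Gpi (0.51) and Pon3 (0.15), the ribosomal proteins Rps15 (0.16) and Rpl41 (0.10), the insulin receptor substrate Irs1 (0.36, 0.548 without a pseudocount and 0.184 within numbers 6 and below), protein S, encoded by Pros1 (0.23), and the adhesion molecule Icam1 (0.64) rose. Prodh (-0.72), Cbs (-0.62), Shmt2 (-0.46), Pgk1 (-0.37), Mdh2 (-0.25), Lrp1 (-0.36), the prolactin receptor Prlr (-0.49), Mbl2 (-0.21) and the acute phase protein Orm1 (-0.29) fell. Their limma adjusted p ran from 0.0013 to 0.0304. The calls of Glud1, Gpi, Pon3, Rps15, Rpl41, Irs1, Cbs, Shmt2, Mdh2, Lrp1 and Mbl2 were lost without control 1 (adjusted p from 0.0544 to 0.17). Those of Glud1, Shmt2, Mdh2, Lrp1, Mbl2 and Prlr were lost without control 2, and those of Rps15, Rpl41, Irs1 and Mdh2 without control 9, and Rpl41 also without high-dosed animal 3 (highest adjusted p of Prlr, Mdh2 and Irs1 0.0547, 0.103 and 0.123). After median centring those of Rps15, Rpl41, Irs1, Glud1, Pros1, Mdh2 and Pon3 were lost (adjusted p from 0.0503 to 0.298), and without a variance trend those of Rps15, Rpl41, Glud1, Mbl2 and Pon3 (adjusted p from 0.0565 to 0.175).

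In total, 8 of the 42 lists were called with the preset correlation, 4 higher and 4 lower. With an estimated correlation camera called 0 (lowest adjusted p = 0.125, 4 lists at an unadjusted p below 0.05), and fry, which tests whether a list's genes move one way on balance, called 7, the Nrf2 and p53 lists among them. Of the 8 lists, fry did not call CAR and PXR targets, macrophages or PPAR alpha targets (adjusted p = 0.0947, 0.18 and 0.669). The list scores gave 0 lists after adjustment and 11 at an unadjusted exact permutation p below 0.05. Of these, 4 lists stood at the smallest possible p of 0.00606, which came to 0.0636 after adjustment, so the count of 0 says little. Of 100 ways of splitting the 11 arrays into 3 and 8, 64 gave at least 8 lists by the same camera test. The 34 lists not called had adjusted p from 0.0618 to 0.978. In 15 of the 42 the mean fold change and the test against the other genes differed in sign, 0 of them among the 8 called.

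The median SD over probe sets was 0.147 among the 8 high-dosed animals and 0.112 among the 3 controls, a ratio of 1.3 that was not tested. A sample SD from 3 animals tends to lie lower than that from 8, so a larger spread among high-dosed animals was not shown. The first principal component (32.3% of the variance) set high-dosed animals 8, 10 and 11 (17.8 to 27.3) apart from the other 8 arrays (-20.7 to -1.49), and their median intensities of 149, 153 and 149 were the lowest. The second component (20.4%) had the 3 controls between -16.0 and -14.8 and the high-dosed animals between -7.27 and 20.2. High-dosed animal 2 had the highest beta-actin 3' to 5' ratio, 2.74 against 1.99 to 2.37 in the other arrays. The ratios of high-dosed animals 8, 10 and 11 (1.992 to 2.145) lay below those of all 8 other arrays (2.154 to 2.742).

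**Figure D3:**
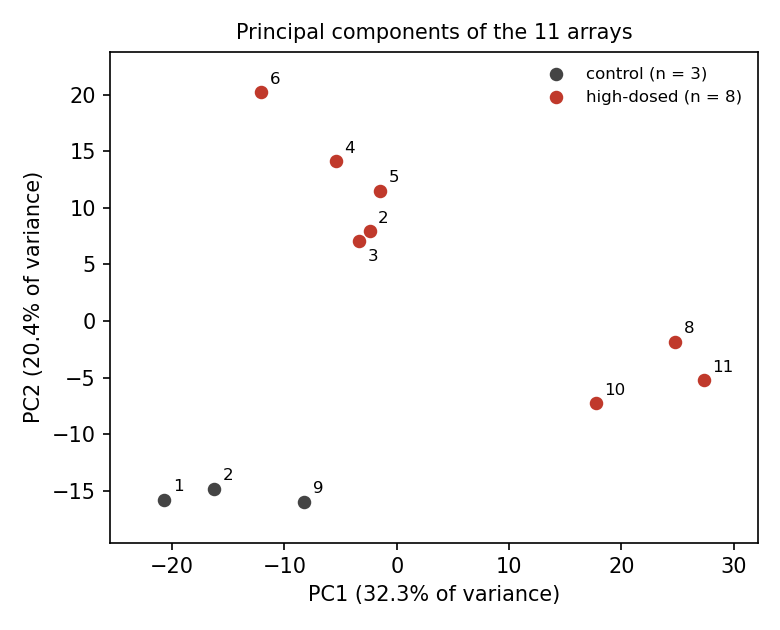
The 11 arrays on the first principal component (horizontal axis, 32.3% of the variance) and the second (vertical axis, 20.4%), with controls in grey (n = 3), high-dosed animals in red (n = 8) and the animal number beside each point. High-dosed animals 8, 10 and 11 lay apart on the first component and the 3 controls at the lowest values of the second.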

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

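The tests of array scaling, time of day, feeding and degraded RNA, the second component of the brighter probe sets, the animal number block and the grouping of clock genes into daytime and night were chosen only after the result was seen. A high-dosed animal is given here when its gap to the nearest of the other 7, divided by the group's range, exceeded the 95% critical value for 8 samples. Of 152 genes, list scores and array measures 11 did so, where chance gives about 7.6. Animal 10 stood apart for Nr1d2 (ratio 0.543; log2 signal 10.59 against 11.10 to 11.53), for Hsd17b2 (0.599; 12.37 against 13.33 to 13.97) and for the MHC class II score (0.538; 0.57 against -0.060 to 0.23). Animal 2 was low for Psmd14 (0.75; 9.95 against 10.35 to 10.48), Hspe1 (0.57; 12.93 against 13.05 to 13.13) and the list scores of phase II conjugation (0.63; -0.16 against -0.0096 to 0.079) and of the p53 response (0.537; -0.063 against 0.0069 to 0.067). Animal 4 was high for Glud1 (0.534; 13.63 against 13.49 to 13.55). Animal 8, labelled with another age, was low for the score of fatty acid and triglyceride synthesis (0.702; -0.21 against -1e-04 to 0.091). The array of animal 11 had the highest Phe spike-in signal among the high-dosed animals (0.556; 951 against 529 to 716) and the lowest median rank correlation with the other arrays (0.608; 0.976 against 0.984 to 0.989).

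Clock genes moved in opposite directions: the mean of 5 daytime genes minus that of 5 night genes was 3.12 higher in high-dosed animals (control SD 0.027). These sets were put together after the opposite movements had been seen, so the difference is a description and not a test. For 5 dusk genes the difference from controls was -0.535, with high-dosed animals from -1.03 to 0.143. After quantile normalization the daytime genes on their own kept 100.4% of their difference (1.98 against 1.97) and the night genes 102.9% (-1.18 against -1.15). The median intensity per array averaged 169.8 in controls and 164.2 in high-dosed animals. With medians so close, this normalization could hardly have removed changes of this size, so the percentages say little about array scaling. Tissue collected at another time of day cannot be told apart from an effect of the drug on the clock, since the labels give no time and every high-dosed animal was shifted, the least by 1.26. Reduced feeding cannot be told apart either, since the PPAR alpha and fatty acid oxidation score differed by -0.0729 (exact permutation p = 0.558) with members moving both ways.

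The proteasome list score, a mean over 30 genes of which 14 fell one by one, was lower in all 8 high-dosed animals than in all 3 controls. After quantile normalization 109% of the score difference was left (exact permutation p = 0.00606), which argues against array scaling. With the beta-actin 3' to 5' ratio as a covariate the group coefficient was -0.209 ± 0.028 (SE), against a difference of -0.21 without it. That ratio averaged 2.221 in controls and 2.271 in high-dosed animals. With means so close the covariate could hardly change the coefficient, so the fit adds little on RNA quality. With the animal number as a block the group coefficient was -0.21 ± 0.025. A difference in collection time or feeding was not tested for these genes and stays open beside an effect of the drug. Collection time, which the labels do not give, stays open for the other genes and lists reported here as well.

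High-dosed animals 8, 10 and 11 lay apart on the first principal component, with a gap to the other arrays of 0.401 of the range. The gap was 0.263 after quantile normalization, which argues against scaling as the whole cause, and 0 of the 3 arrays had a beta-actin ratio above the median of the other 8, which argues against degraded RNA as a higher ratio would show it. All 3 ratios (1.992 to 2.145) lay below those of the other 8 arrays (2.154 to 2.742), so a difference in RNA quality in the other direction stays open. For dim probe sets, the test set in advance gave a gap of -0.119 on the first component of the brighter probe sets, as dim signal as the cause would, but that component followed the treatment (r = 0.97 with group, 0.456 with the 3 arrays) and so decides nothing. The second component of the brighter probe sets had a gap of 0.223, but was chosen after it was seen, and the dimmer ones carried 65.7% of the squared loadings of the first component of all, so dim signal stays open. These are 3 of the 4 animals numbered 8 or above. Control 9, also in that range, lay at -8.22 on the first component, among the other arrays, so the number range alone did not set them apart. Both groups held an animal 2, so the numbers may not follow a shared order. Handling shared by the 3 arrays stays open with no label to test it, and no biological explanation was tested.

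The counts were set beside 100 splits of the 11 arrays into 3 and 8, the real one included. For probe sets (1288) and for genes (1141) 2 of the 100 splits gave as many, the real split and 1 other, so few groupings reached these counts. Because a grouping that put all controls together with other high-dosed animals gave more, the counts alone do not tell an effect of the drug from another structure of the samples. The other split, of high-dosed animals 8, 10 and 11 against the rest, gave the highest counts, 4636 probe sets and 2068 genes, which points to a structure of the samples. All 3 were treated animals, so whether that structure was unrelated to treatment is not known. With the animal number as a block the real comparison called 1955 probe sets and 1520 genes, within numbers 6 and below 761 and 612, and within 8 and above 17 and 3. For gene lists 64 splits gave at least the real 8 and the highest other gave 20, so chance cannot be excluded for that count.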

How the results depend on the processing

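The settings on animal numbers, on animals 8, 10 and 11 and on the beta-actin ratio were chosen only after seeing the data. With each array left out in turn the probe sets changed ranged from 324 (without control 1) to 1688 (without high-dosed animal 2), with 218 to 1215 higher and 106 to 473 lower. The genes changed ranged from 325 to 1406, with 246 to 1081 higher and 79 to 325 lower, the lists shifted from 7 to 11 and the named genes called from 45 to 80. Without 1 high-dosed animal 832 to 1406 genes were called. Of 79 called genes named by the rule 38 kept their call in all planned settings and 39 without each single array; 35 lost it without control 1, 17 without control 2, 15 without control 9 and 6 without a high-dosed animal. With the added settings 2 kept it throughout, and 0 of the 79 changed direction in any setting, which their being called on the same arrays made likely. Median centring gave 530 higher probe sets, 731 genes changed and 473 higher genes. Lists shifted numbered 13 without a filter, 0 with an estimated correlation and 16 with animals 8, 10 and 11 left out, a setting that gave 553 higher probe sets, 716 genes changed and 506 higher genes and ended the calls of Cyp17a1, Hspa4, RT1-Da, RT1-DMb, RT1-DMa, Mrc1, Abcc3, Decr2, Cpt1a, Lrp1, Rps15, Rpl41, Irs1, Mbl2, Asgr1 and Ccng1 (adjusted p from 0.0526 to 0.123), and among genes named after their values were seen those of Per1, Mocs1, Nfe2l2, Zmat3, Mgmt, Bub1, Tyms and Acads (adjusted p from 0.0556 to 0.125). The animal number block called 1955 probe sets, 714 of them lower. Numbers 6 and below alone gave 761 probe sets (449 higher), 612 genes (408 higher) and 51 named genes. Numbers 8 and above alone, with 1 control, gave 17 probe sets (9 higher, 8 lower), 3 genes (2 higher, 1 lower) and 2 named genes, with a mean of the ER stress list of -0.23. There 17 of the 79 called named genes were smaller by over 1.5 times, among them Lifr (-0.979), Bmal1 (-1.03), Abcg5 (-1.21) and Nat8 (-0.772), and 2 were larger, Apoa1 (0.583) and Irs1 (0.673), while Irs1 was 0.184 within numbers 6 and below (adjusted p = 0.152). The cause was not tested. In the other settings each count stayed within 1.5 times, and the exact permutation test put 1443 probe sets at its smallest p, where chance gives 113.

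Of the results whose sign turned, the PPAR alpha list (0.133 within numbers 8 and above) was called in the main setting and the others in neither. That covers the 17 lists with values of their own; of the other 25, 13 turned sign in at least 1 setting (56 results), 0 of them called in the main setting and 1 where it turned, amino acid catabolism without animals 8, 10 and 11 (0.000226, adjusted p = 0.0411). Within numbers 8 and above the clock list's mean was -0.0642, the hepatocyte list's 0.00554, Cyp4a1 0.141 and Gclc 0.0491. Pck1 was -0.0064 and Alb -0.0201 after median centring, Alb was -0.00362 within numbers 6 and below, and the hepatocyte mean was 0.00406 without animals 8, 10 and 11. With single arrays left out the hepatocyte mean ran from -0.00933 to 0.00321, Cyp4a1 from -0.0829 to 0.11, Gclc from -0.162 to 0.0106, Pck1 from -0.0245 to 0.0504 and Alb from -0.0099 to 0.00775. The cause was not tested. Of the 34 lists not called, 12 were called in at least 1 setting, most often Nrf2, bile acids and ribosomal proteins (7 settings each). Camera has no robust variance option, so that setting was not run for lists. No paired analysis was possible because the groups shared 1 animal number. The values carried no detection calls, so how far dim signal lay above background is unknown and the filter was the only limit on it.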

Other observations

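All genes and relations in this part were chosen only after the result was seen. Hsd11b1, which regenerates active glucocorticoid, rose 2.16-fold (log2 fold change 1.11 ± 0.26, limma adjusted p = 0.0183), and Nr1i3, encoding the receptor CAR, rose by 1.08 ± 0.25 (limma adjusted p = 0.0194). Fmo1 had the smallest limma adjusted p of the genes in this part (1.33 ± 0.11, 6.06e-05). Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, rose by 0.99 ± 0.14 (limma adjusted p = 0.00182), the pro-apoptotic Bcl2l11 by 1.01 ± 0.18 (limma adjusted p = 0.00477) and the DNA helicase Blm by 0.96 ± 0.10 (limma adjusted p = 0.000313). Fkbp4, a cochaperone of steroid receptors, fell by 0.87 ± 0.087 (limma adjusted p = 0.000313). All 8 high-dosed animals lay on the same side of the control mean for each of these 7 genes. The calls of Hsd11b1 and Nr1i3 were lost without control 2 or 9 (highest adjusted p = 0.0812 and 0.0938), and the others were kept without each single array.

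A hypothesis was that animals with a larger clock shift had a larger fall of proteasome genes. Across the 8 high-dosed animals Pearson's r between the daytime-minus-night score and the proteasome score was -0.405 (exact permutation p = 0.328, adjusted 0.524 over 8 lists) and Spearman's rho -0.476 (exact permutation p = 0.243, adjusted 0.576). Without animals 10 and 3, the farthest from the median clock score, r was 0.273, so no relation was shown. Among the 8 called lists the lowest p was for the ER stress score (r = 0.864, exact permutation p = 0.00737, adjusted 0.0589; rho 0.857, exact permutation p = 0.0107, adjusted 0.0857), which did not pass adjustment and was 0.539 without those 2 animals. The number ranges held 5 and 3 high-dosed animals, and no correlation was computed within either.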
